A study of Mus spretus with 19 samples.

How the data were processed

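Pooled liver RNA of Mus spretus from 5 sites (1 pool of 9 male mice per site) was labelled with Cy3 and hybridized to 19 one-colour Agilent mouse arrays with 45018 spots each, 4 arrays per site and 3 for DR6. The probes were designed for Mus musculus, so a sequence difference between the species can lower a probe's signal. Whether such differences were the same in the mice of all sites was not tested. Per the labels, the arrays of a site are technical repeats of 1 pool, and per the file headers the arrays of each site shared 1 slide and 1 scan, 5 slides and 5 scans in all.

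The deposited scanner files hold, per the file headers, the linear intensity of each spot: the authors ran Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes, which subtracts the background, corrects spatial trends and gives a surrogate intensity to spots not above background. The mean spot intensity and the median local background intensity in the same deposited files are raw. The other deposited columns used are flags of the extraction software, of 0 or 1: well above background, saturated, outlier and control spot. The authors did not scale the arrays to each other. The deposited table of the whole series holds linear intensity per array, not centred, with column medians from 9.72 to 24.8. Comparison with the scanner files showed it to be the same signal rounded to 3 significant digits, with a largest relative difference of 0.497%. The DR1 slide was extracted with an older design file, in which 5.84% of gene spots carry another gene name, so all gene names were taken from the newer file (annotation of the mm8 mouse build) through the probe. The files pair probes with symbols themselves, and 11792 of the 16346 genes and transcripts tested have a symbol. No genome was used, and symbols are printed as the files give them.

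Of the spots, 1639 controls were left out, which left 43379 gene spots of 41174 probes. The processed signal was put on the log2 scale and the 75th percentile of each array was subtracted. Outlier spots were set missing and spots of 1 probe averaged. A probe was kept when it was well above background on at least 3 arrays of at least 1 site, 23458 probes, and each gene was represented by its brightest kept probe. All 19 arrays measured 16003 genes, and 343 had an outlier spot on 1 or more arrays. The depth of an array is its signal over background: the 75th percentile of the signal ran from 99.5 to 285.2 between arrays, and 52.0% to 61.5% of spots were well above background. The number of arrays limits the precision, and a gene at background in the lower site has only a bound.

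A linear model with a mean per site was fitted to all arrays with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment over all genes within each comparison. The 7 comparisons were each polluted site against SOL and the 3 pairs of stream sites. A call needed an adjusted p under 0.05 and a 2-fold change, 1 on the log2 scale. All tests are two-sided. A second fit used the 5 site means as units, for the polluted sites against SOL and for each site against the mean of the other 4. It has no replicate pools at any single site, so the lone pool is assumed to vary like the others. A count of genes that differ in the same direction from all 4 other sites was added after the data were seen. The overlap of the 4 site comparisons was set against 20 simulations. The correlation of their changes was computed again with the SOL arrays divided between the comparisons.

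Before the data were examined, 36 gene lists (pathways, stress responses and markers of cell types and of exocrine pancreas), the comparisons, the filter, the limits, the alternatives and the rule for named genes were fixed. Some genes are on more than 1 list, so lists are not separate evidence. Acot3 and Acot4 are on the PPARα and the female-biased lists. The p53 list, also called p53 targets below, also holds genes of DNA damage. Lists were tested with limma's camera, with the preset correlation of 0.01 between genes and again with the correlation estimated from the data, adjusted over the 36 lists within a comparison. On the arrays this correlation was estimated from technical repeats, so it does not hold the spread between mice or pools. For cholesterol synthesis it was 0.0286 on the arrays and 0.743 with pools as units. For exocrine pancreas it was 0.00131 and 0.981. On the arrays, camera used only members with a value on every array. The counts and medians printed beside its p-values use all measured members. For PS against SOL it used 27 of 35 PPARα targets, 21 of 25 cholesterol synthesis genes, 41 of 51 oxidative phosphorylation genes and 5 of 6 AHR targets. The rule named the 10 largest rises and 10 largest falls in each site comparison, among called genes with a symbol that were well above background on all arrays of the higher site. It also named the 12 and 12 with the largest smallest change among those called at all 4 sites, 5 and 5 in each stream comparison, at most 4 members of each list (called ones first, by the size of their mean change), and always Mt1, Mt2, Cyp1a1, Cyp1a2, Cyp2b10, Hmox1 and Nqo1, 215 genes in all. Of 423 calls of named genes, 108 had another kept probe, of opposite sign in 3. A further 7 lists of other organs, with 73 measured genes, were chosen after the named genes were seen. Medians of lists with members at their bound were added after the data were seen.

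The scripts were tested on simulated data with 50 changed genes per fold among 16346. At a true 1.5-fold change the array fit called 0% of them in each comparison, which the 2-fold limit of a call largely sets. On the adjusted p alone, 50% (DR1 against DR4) to 80% (PS against SOL) of them passed at 1.5-fold. At 2-fold, 78% (DR6 against SOL) to 94% (DR4 against SOL) of them did. At a true 2-fold change the array fit called 44% of them for PS against SOL, 48% for DR1, 42% for DR4 and 40% for DR6 against SOL, 42% for DR1 against DR6, 40% for DR4 against DR6 and 58% for DR1 against DR4. At 3-fold it called 96%, 96%, 100%, 86%, 94%, 94% and 96% in the same order, with 2, 1, 0, 2, 1, 0 and 1 false calls. The fit of pools for polluted sites against SOL called 0% at 2-fold, 46% at 4-fold, 84% at 16-fold and 90% at 64-fold, with 7 false calls. For PS against SOL both lists given a shift were found with either correlation, and 1 other list was called with the preset and 0 with the estimated correlation. The simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely.

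The alternatives were quantile scaling, median scaling, normexp background correction (offset 50) with quantile scaling, the series value table, no filter on dim probes, only probes well above background on all arrays, the mean of all probes of a gene, a block for replicate number, a fit on the arrays of the 2 sites alone, calls on the adjusted p alone, a test against a 1.5-fold change (treat) and leaving out each array in turn. For the fit of pools, each polluted pool was left out in turn and the arrays were used as replicates. Chosen after seeing the data were leaving SOL out of the fit of pools, leaving out both arrays with a mean correlation under 0.985 with their site, and leaving out genes of exocrine pancreas and the other-organ lists. Scaling moved the median change of all genes by at most 0.096. Lists were also compared with 10000 random lists of genes matched on signal. Each gene of a random list was drawn separately, so a list whose members vary together can lie at the end for any cause. No array was left out of the reported results.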

Results

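Liver RNA of male Algerian mice (Mus spretus) from 5 sites in southwest Spain was measured on 19 mouse expression arrays. The Santa Olalla lagoon (SOL) served as the unpolluted site. The 4 polluted sites were the phosphogypsum stacks (PS), which are dumps of fertilizer waste, and the lower, medium and upper course of the Domingo Rubio stream (DR1, DR4 and DR6). For each site the livers of 9 mice were pooled into 1 RNA sample, which was hybridized to 4 arrays, of which DR6 has 3. The arrays of a site are therefore technical repeats: the tests below measure a difference against the spread of labelling and hybridization, not against the spread between mice. The arrays of each site shared 1 slide and 1 scan, so a site and its slide cannot be told apart. Arrays of the same site correlated at r = 0.98 to 0.997 across genes, and arrays of different sites at 0.952 to 0.984; genes are not independent replicates. Between 52.0% and 61.5% of the gene spots of an array were well above background, with a mean of 53.9% ± 2.04 (SD, n = 4) at SOL, 55.2% ± 0.813 (n = 4) at PS, 55.2% ± 2.12 (n = 4) at DR1, 57.6% ± 2.66 (n = 4) at DR4 and 54.1% ± 0.821 (n = 3) at DR6. The number of arrays limits the precision.

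Changes are log2 fold changes with their standard error (SE) from limma, with n = 4 arrays per site and 3 at DR6. A gene was called when its adjusted p was under 0.05 and it differed at least 2-fold. A gene not well above background on any array of the lower site, or saturated on every array of the higher one, has only a bound, made with the lowest signal that counted as well above background on each array and written "at least". The largest rises and falls below were ranked by fitted change. A gene with only a bound thus has a place in that order but no measured size, and measured genes not named can exceed its bound. Of 16346 genes and transcripts tested, 722 differed between PS and SOL, 994 between DR1 and SOL, 1722 between DR4 and SOL and 1136 between DR6 and SOL.

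**Figure D1:**
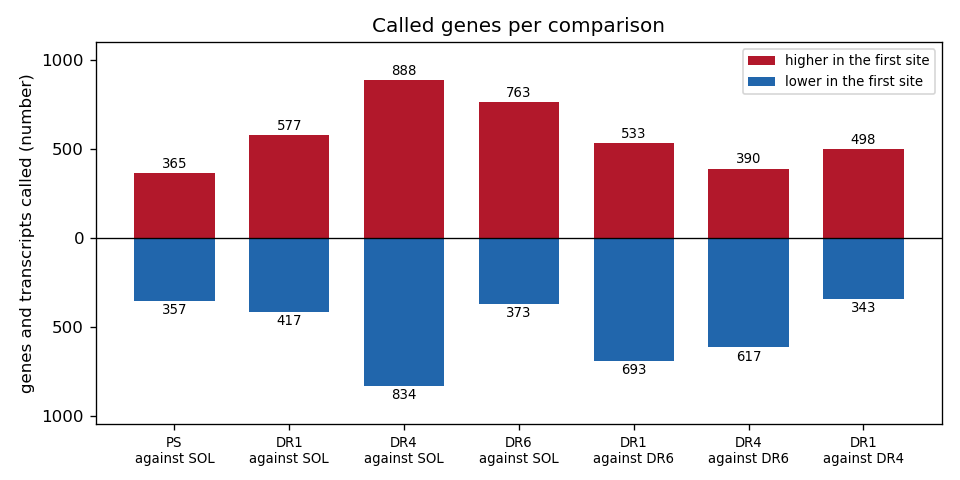
Number of genes called higher (upward bars) and lower (downward bars) in each of the 7 comparisons of sites, out of 16346 genes and transcripts tested. DR4 against SOL had the most calls, 888 higher and 834 lower, and PS against SOL the fewest, 365 higher and 357 lower.

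The first comparison asked how livers from the phosphogypsum stacks differed from those of the unpolluted lagoon. Genes of cholesterol synthesis fell as a group at PS: 18 of 25 measured members fell and none rose, with a median of −1.97 (adjusted p = 6.49e-26). Idi1 fell by 3.51 ± 0.074 and Fdps by 2.81 ± 0.076, both enzymes that build the isoprenoid precursors of cholesterol. Fatty acid synthesis fell with it, 8 of 21 members (median −0.88, adjusted p = 3.49e-09), among them Thrsp at −2.27 ± 0.073, Fasn at −1.82 ± 0.080 and Elovl6 at −1.31 ± 0.059. Fdps is 1 of the genes whose call depends on the probe: the mean of all its probes gave −0.97 (adjusted p = 0.434).

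Interferon response genes rose at PS, 7 of 33 (median 0.33, adjusted p = 6.14e-06), with Ifi27 at 1.30 ± 0.079, Rsad2 at 1.24 ± 0.13 and Ifit1 at 1.16 ± 0.20. B cell and plasma cell markers rose as well, 4 of 10 (median 0.86, adjusted p = 0.00017), with Cd79b, a part of the B cell receptor, at 1.80 ± 0.11. T and NK cell markers had 3 of 19 members higher (median 0.56, adjusted p = 0.00182), a call that was lost at adjusted p = 0.0879 with an estimated correlation. Of the acute phase genes 4 of 29 rose, led by the protease inhibitor A2m at 3.83 ± 0.080 (adjusted p = 2.64e-15) and by Saa3 at 2.15 ± 0.083. The acute phase list as a whole had a median of 0.19 (adjusted p = 0.00636), lost at adjusted p = 0.320 with an estimated correlation. Without SOL replicate 1 the value of Ifit1 was 0.94, under the 2-fold limit, and the mean of all probes of Rsad2 gave 0.96.

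The metallothionein gene Mt1, which encodes a metal-binding protein induced by metals and stress, rose by 1.36 ± 0.11 at PS, but its call rests on the brightest probe, since the mean of all its probes gave 0.71. Mt2 stood at 0.88 ± 0.13, under the 2-fold limit. Hamp1, the iron hormone hepcidin, rose by 1.20 ± 0.14, the transferrin receptor Tfrc fell by 1.25 ± 0.047 and the zinc transporter Slc39a5 changed by −1.72 ± 0.27. The whole metal list had 2 members higher and 2 lower of 22, a median of −0.02 and no call (adjusted p = 0.623). Other genes of xenobiotic response stayed under the limit: Cyp1a1 at 0.73 ± 0.18, Cyp1a2 at 0.71 ± 0.065, Cyp2b10 at 0.11 ± 0.081, Hmox1 at 0.09 ± 0.089 and Nqo1 at 0.27 ± 0.095. The plasma glutathione peroxidase Gpx3 rose by 2.89 ± 0.13, and the aldo-keto reductase Akr1b8 by 1.64 ± 0.072.

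Male-biased liver genes were higher at PS, 3 of 15 up and 1 down (median 0.18, adjusted p = 0.00552), among them Cyp4a12 at 1.97 ± 0.068 and the major urinary protein Mup5 at 2.64 ± 0.11, while Elovl3 stood at 0.11. Female-biased genes were lower, 4 of 19 down and 1 up (median −0.47, adjusted p = 0.00113), among them Hao3 at −2.20 ± 0.12. PPARα targets had a median of −0.28 over 35 members (adjusted p = 2.67e-07), with 1 higher and 1 lower. Glutathione S-transferases had a median of −0.26 with none of 21 past 2-fold (adjusted p = 0.00894), and p53 targets one of 0.16 with 1 of 24 lower (adjusted p = 0.00552). These 5 calls held with an estimated correlation, as did those for cholesterol, fatty acids, interferon, B cells and exocrine pancreas. Here and below that correlation comes from technical repeats. A call that held with it was not tested against the spread between mice or pools. The calls that did not hold were CAR and PXR targets (median −0.33, 3 of 26 lower, adjusted p = 0.00502; adjusted p = 0.0879 with an estimated correlation), ER stress (median 0.31, adjusted p = 0.0222; adjusted p = 0.0578 with an estimated correlation), cell cycle (median −0.10, adjusted p = 0.014; adjusted p = 0.0578 with an estimated correlation), urea cycle and amino acid breakdown (median 0.16, adjusted p = 0.0107; adjusted p = 0.0646 with an estimated correlation) and ribosomal proteins (median 0.15, adjusted p = 0.0014; adjusted p = 0.210 with an estimated correlation).

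Transcripts of other organs moved in the same pool. Exocrine pancreas markers fell, 13 of 14 (median −2.05, adjusted p = 3.83e-22), with Ela2a at −2.47 ± 0.051 and Cel at −2.40 ± 0.13. The islet hormones Gcg, at least 6.06-fold lower, and Ins2, at −3.15 ± 0.11, fell too. Chgb, a protein of neuroendocrine granules, was at least 46.6-fold higher, and Kap, a protein of kidney tubules, at least 10.5-fold higher. The other genes with the largest fitted rises were the chitinase-like genes Chi3l3 (at least 24.7-fold) and Chi3l4 (at least 5.96-fold), Xlr4b (at least 6.84-fold), Cyp26a1 (at least 7.77-fold), Rnf183 (at least 5.60-fold), Reg3a at 3.66 ± 0.083 and Ugt2b35 at 3.26 ± 0.48. The largest fitted falls also included carbonic anhydrase 3 (Car3) at −3.91 ± 0.084, the cadherin Cdh11 (at least 5.89-fold), the intestinal defensins Defa1 (at least 3.02-fold) and Defcr6 (at least 2.06-fold), Agr2 (at least 2.92-fold) and Ccl28 (at least 2.61-fold).

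Of the 722 genes called between PS and SOL, 365 were higher and 357 lower, 484 had a gene symbol and 185 rested on a bound. A further 16 were not above background at either site, so those calls rest on no measured signal. The share of calls that were higher was 50.6%, 59.4% under median scaling, 56.8% under quantile scaling and 42.9% under normexp. At the adjusted p alone, 5364 genes passed. With normexp background correction and quantile scaling 43 of the 82 named genes that were called here lost their call, among them Tfrc (−0.82), Cd79b (0.69), Rsad2 (0.76), Ifit1 (0.59), Slc39a5 (−0.35) and Ugt2b35 (0.59).

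The lists without a call at PS had these medians. NRF2 targets stood at −0.00 with a mean of 0.15 and an upward test (adjusted p = 0.348), antioxidant enzymes at −0.06 with a mean of 0.06 and a downward test (adjusted p = 0.386), AHR targets at 0.13 (adjusted p = 0.111), MHC class II at 0.04 (adjusted p = 0.667) and heat shock at −0.09 (adjusted p = 0.0599). Gluconeogenesis and glycolysis stood at −0.21 (adjusted p = 0.162), bile acid genes at −0.00 with a mean of 0.02 and an upward test (adjusted p = 0.908), clock genes at −0.07 (adjusted p = 0.503), complement and coagulation at −0.09 (adjusted p = 0.348), oxidative phosphorylation at −0.08 (adjusted p = 0.195) and immediate early genes at −0.06 (adjusted p = 0.420). Under median scaling the medians of the antioxidant, clock, oxidative phosphorylation and immediate early lists at PS changed sign. Markers of hepatocytes stood at −0.22 (adjusted p = 0.236), macrophages at 0.13 (adjusted p = 0.148), neutrophils at 0.32 (adjusted p = 0.135), erythroid cells at 0.20 (adjusted p = 0.447), stellate cells at −0.03 (adjusted p = 0.356), endothelium at 0.00 with a mean of −0.01 (adjusted p = 0.524) and cholangiocytes at −0.15 (adjusted p = 0.356).

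The second comparison set the lower course of the stream, DR1, against the lagoon. Immediate early genes, which are switched on within minutes of a stimulus, rose at DR1, 7 of 22 and none lower (median 0.79, adjusted p = 6.04e-06). Nr4a1 rose by 3.23 ± 0.062, Fos by 2.55 ± 0.12, Myc by 1.64 ± 0.055 and Btg2 by 1.4 ± 0.068. Genes of the p53 and DNA damage list rose with them, 10 of 24 (median 0.91, adjusted p = 2.05e-08), with Sesn1 at 2.51 ± 0.076, Trp53inp1 at 2.18 ± 0.078 and Gadd45b at 1.75 ± 0.060. Btg2 and Gadd45g are members of both lists. PPARα targets, which serve fatty acid oxidation, fell: 9 of 35 (median −0.57, adjusted p = 2.05e-08), with the acyl-CoA thioesterases Acot2 at −1.98 ± 0.062 and Acot3 at −1.40 ± 0.073. Fatty acid synthesis fell, 3 of 21 (median −0.57, adjusted p = 6.99e-05), with Thrsp at −1.84 ± 0.073.

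Targets of the aryl hydrocarbon receptor rose at DR1, 3 of 6 (median 1.08, adjusted p = 0.000151): Cyp1a2 by 1.5 ± 0.065, Cyp1a1 by 1.28 ± 0.18 and Tiparp by 1.93 ± 0.11. Mt1 rose by 2.21 ± 0.11, Mt2 by 1.13 ± 0.13 and Hamp1 by 1.95 ± 0.14, while Tfrc fell by 1.10 ± 0.047 and Slc39a5 changed by −2.08 ± 0.27. The metal list as a whole had 6 of 22 members higher and 3 lower, with a median of 0.27 and no call (adjusted p = 0.346). Values for Nqo1 (0.89 ± 0.095), Cyp2b10 (0.27 ± 0.081) and Hmox1 (0.27 ± 0.089) were under the limit. With normexp and quantile scaling Cyp1a1 (0.55), Tfrc (−0.75) and Slc39a5 (−0.44) fell under the limit.

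Male-biased liver genes rose at DR1, 7 of 15 (median 0.52, adjusted p = 0.000346), with Cyp4a12 at 3.1 ± 0.068, Mup5 at 3.23 ± 0.11 and the fatty acid elongase Elovl3 at 2.95 ± 0.054. Female-biased genes fell, 6 of 19 (median −0.50, adjusted p = 0.000514), with Hao3 at −1.74 ± 0.12 and the peroxisomal transporter Abcd2 at −1.65 ± 0.19. Erythroid markers fell, 2 of 11 (median −0.62, adjusted p = 0.00238), with the globin gene Hba-a1 at −1.23 ± 0.068. Heat shock genes fell, 3 of 21 (median −0.15, adjusted p = 0.0194), with Hspa1b at −1.45 ± 0.091 and Hspa1a at −1.07 ± 0.067. Under normexp and quantile scaling Abcd2 (−0.67), Hba-a1 (−0.93), Hspa1b (−0.60) and Hspa1a (−0.70) lost their calls. All of these list calls held with an estimated correlation. CAR and PXR targets (median −0.36, adjusted p = 0.00495) did not hold, at adjusted p = 0.109 with an estimated correlation, nor did B cell markers (median 0.38, adjusted p = 0.0213), at adjusted p = 0.0552 with an estimated correlation.

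The cell cycle list at DR1 had 12 of 26 members higher and 2 lower and a median of 0.84, yet no call (adjusted p = 0.0629). Ccnb2, a cyclin of cell division, rose by 2.07 ± 0.18 and Mcm5, a DNA replication helicase, fell by 1.32 ± 0.095. Acute phase genes had a median of −0.26 with a mean of 0.18 and a downward test (adjusted p = 0.470), although A2m rose by 3.32 ± 0.080 and Saa3 by 1.70 ± 0.083. The list median changed sign under quantile scaling. Gluconeogenesis had a median of 0.01, a mean of −0.01 and an upward test (adjusted p = 0.819). Cholesterol synthesis had a median of −0.22 (adjusted p = 0.0629). The collagens Col3a1 and Col1a1 rose by 1.32 ± 0.081 and 1.18 ± 0.11, and the matrix proteoglycan Lum by 1.59 ± 0.059, in a stellate cell list that was not called (adjusted p = 0.494). The bile acid enzyme Cyp7b1 rose by 1.29 ± 0.075, the lipin Lpin1 by 1.67 ± 0.063 and the stress gene Ddit4 by 1.72 ± 0.087, and pyruvate kinase, Pklr, fell by 2.0 ± 0.16. Under normexp and quantile scaling Col3a1 (0.87), Col1a1 (0.62), Lum (0.62), Mcm5 (−0.57) and Pklr (−0.87) lost their calls at DR1.

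Exocrine pancreas markers fell at DR1, 3 of 14 (median −0.84, adjusted p = 3.05e-07), with Ela2a at −2.11 ± 0.051 and Ctrb1 at −1.40 ± 0.11. The largest fitted rises at DR1 were in Reg3a (5.23 ± 0.083) and Pap (4.49 ± 0.090), secreted lectins of gut and pancreas, with Reg3g (at least 3.86-fold) and Reg3d (at least 5.04-fold). The growth factor Btc rose by 3.34 ± 0.10. Chi3l4 was at least 7.51-fold, Chi3l3 at least 13.7-fold, Chgb at least 14.3-fold, the lung surfactant gene Sftpc at least 5.43-fold and Cyp26a1 at least 9.79-fold higher. The largest fitted falls were in Ddx25 (−3.28 ± 0.23), Cdh11 (at least 6.0-fold), Trim55 (−2.41 ± 0.26), Slco4a1 (−2.35 ± 0.17), Emilin3 (at least 3.68-fold), Ypel4 (at least 2.17-fold), Chrna2 (−2.26 ± 0.34), Mfsd7 (−2.17 ± 0.22), Pctp (−2.13 ± 0.14) and Soat2 (−2.12 ± 0.091). Of 994 genes called 577 were higher and 417 lower, 700 had a symbol, 242 rested on a bound, 8 had no signal above background at either site, and 7796 passed the adjusted p alone. With normexp and quantile scaling 50 of the 100 named genes that were called lost their call, and 11 did when 1 array was left out.

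The third comparison set the medium course, DR4, against the lagoon and gave the most calls. PPARα targets fell, 18 of 35 down and 1 up (median −1.04, adjusted p = 2.96e-11), with Acot3 at −2.74 ± 0.073, Acot2 at −2.29 ± 0.062 and the fasting hormone Fgf21 at −3.20 ± 0.41; the member that rose was Cyp8b1, a bile acid hydroxylase, at 1.68 ± 0.11. Immediate early genes rose, 10 of 22 (median 0.85, adjusted p = 4.64e-07), with Nr4a1 at 2.68 ± 0.062, Myc at 2.47 ± 0.055, Btg2 at 1.89 ± 0.068 and Fos at 1.87 ± 0.12. The p53 list rose, 10 of 24 (median 0.84, adjusted p = 4.27e-07), with Sesn1 at 3.24 ± 0.076 and Trp53inp1 at 2.84 ± 0.078. Fatty acid synthesis fell, 5 of 21 (median −0.61, adjusted p = 6.23e-05), with Thrsp at −1.59 ± 0.073 and Elovl6 at −1.46 ± 0.059. Glutathione S-transferases, which detoxify electrophiles, fell, 5 of 21 (median −0.64, adjusted p = 0.000299), with Gstt2 at −1.53 ± 0.088, Mgst3 at −1.31 ± 0.057 and Gstm4 at −1.28 ± 0.082.

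Mt1 and Hamp1 had their largest rises at DR4: Mt1 rose by 2.51 ± 0.11, Mt2, saturated at DR4, was at least 2.34-fold higher, and Hamp1 rose by 2.25 ± 0.14. Slc39a5 changed by −2.57 ± 0.27. The metal list nevertheless had 5 of 22 members higher and 2 lower, a median of −0.07, a mean of 0.12, an upward test and no call (adjusted p = 0.932). Its median changed sign under quantile scaling. AHR targets rose, 3 of 6 (median 0.69, adjusted p = 0.00538): Tiparp by 2.19 ± 0.11, the receptor gene Ahr by 1.64 ± 0.12 and Cyp1a1 by 1.13 ± 0.18, while Cyp1a2 stood at 0.25 ± 0.065. Cyp2b10, the usual marker of CAR activation, rose by 1.85 ± 0.081, in a CAR and PXR list with a median of −0.34 and no call (adjusted p = 0.163; sign changed under quantile scaling). Hmox1 (0.37 ± 0.089) and Nqo1 (0.17 ± 0.095) were under the limit. Gpx3 rose by 4.91 ± 0.13.

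Male-biased genes rose at DR4, 6 of 15 (median 0.38, adjusted p = 0.00496), with Mup5 at 3.28 ± 0.11, Elovl3 at 2.82 ± 0.054 and Cyp4a12 at 2.63 ± 0.068. Female-biased genes fell, 6 of 19 down and 1 up (median −0.42, adjusted p = 0.0041), with Abcd2 at least 13.8-fold lower. Erythroid markers fell, 6 of 11 (median −1.05, adjusted p = 0.000221), with Eraf, the chaperone of alpha globin, at −1.89 ± 0.18, Slc4a1 at −1.59 ± 0.12 and Alas2, the erythroid aminolevulinic acid synthase, at −1.51 ± 0.094. Heat shock genes had a median of −0.39, with 1 of 21 higher and 1 lower (adjusted p = 0.0148), a list call that was lost with normexp and quantile scaling. The calls up to here held with an estimated correlation.

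The DR4 calls that did not hold were macrophage markers (median −0.29, adjusted p = 0.0171; adjusted p = 0.297 with an estimated correlation), in which the scavenger receptor Marco fell by 1.84 ± 0.079 and the Kupffer cell lectin Clec4f by 1.43 ± 0.057, clock genes (median −0.27, adjusted p = 0.0428; adjusted p = 0.0905 with an estimated correlation), complement and coagulation (median −0.29, adjusted p = 0.0171; adjusted p = 0.269 with an estimated correlation), oxidative phosphorylation (median −0.16, adjusted p = 0.0148; adjusted p = 0.166 with an estimated correlation), antioxidant enzymes (median −0.32, adjusted p = 0.021; adjusted p = 0.196 with an estimated correlation) and endothelial markers (median −0.29, adjusted p = 0.0324; adjusted p = 0.0587 with an estimated correlation). Clock genes moved in both directions: Arntl, the activator of the clock, rose by 2.25 ± 0.39, or 1.64 without SOL replicate 1, and its repressor Per2 fell by 2.18 ± 0.15. Interferon genes had a median of −0.29 and no call (adjusted p = 0.839), with Rsad2 at 2.14 ± 0.13 and Mx2 at −1.98 ± 0.093. Acute phase genes had a median of −0.27 with a mean of 0.07 and a downward test (adjusted p = 0.619), and bile acid genes a median of −0.27 with a mean of −0.01 and an upward test (adjusted p = 0.932). The bile acid importer Slc10a1 fell by 1.91 ± 0.072. The acute phase median changed sign with normexp. Cholesterol synthesis had a median of −0.17 (adjusted p = 0.619). The aminotransferase Got1 rose by 2.05 ± 0.063 and Lpin1 by 2.21 ± 0.063. Pklr fell by 2.98 ± 0.16 and the cyclin Ccnd1 by 1.91 ± 0.056.

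All 14 exocrine pancreas markers fell at DR4 (median −2.98, adjusted p = 1.70e-14), and Ela2a (−4.01 ± 0.051), Ela1 (−3.92 ± 0.058), Pla2g1b (−3.63 ± 0.078), Cpb1 (−3.61 ± 0.11), Cel (−3.47 ± 0.13) and Cuzd1 (−3.43 ± 0.072) were among the largest fitted falls of the comparison, with Abcd2, Inhbe (−4.08 ± 0.096), Krt20 (−3.55 ± 0.23) and Defa1 (at least 3.51-fold). The largest fitted rises were in Chi3l4 (at least 21.5-fold), Chi3l3 (at least 47.0-fold), Btc (5.41 ± 0.10), the calcium channel subunit Cacnb4 (at least 15.7-fold), neuropeptide Y, Npy (5.35 ± 0.12), Gpx3, the potassium channel subunit Kcnab1 (4.88 ± 0.12), Tnfaip6 (at least 6.30-fold), Cyp26a1 (at least 18.5-fold) and the growth factor Areg (at least 4.43-fold). Of 1722 genes called 888 were higher and 834 lower, 1218 had a symbol, 295 rested on a bound, 11 had no signal above background at either site, and 8982 passed the adjusted p alone. With normexp and quantile scaling 39 of 116 named genes that were called lost their call, among them Cyp1a1 (0.48), Fos (0.77), Mx2 (−0.90), Slc39a5 (−0.51), Eraf (−0.46) and Slc4a1 (−0.56).

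The fourth comparison set the upper course, DR6, against the lagoon. Immediate early genes rose, 13 of 22 (median 1.12, adjusted p = 3.74e-10), with Atf3 at 3.74 ± 0.087, Btg2 at 3.65 ± 0.073, Nr4a1 at 3.28 ± 0.067, Myc at 2.30 ± 0.059 and Fos at 2.02 ± 0.13. The p53 list rose, 9 of 24 (median 0.69, adjusted p = 1.88e-07), with Trp53inp1 at 2.57 ± 0.084, Sesn1 at 2.43 ± 0.082 and Gadd45b at 2.27 ± 0.065. Interferon response genes fell, 5 of 33 (median −0.38, adjusted p = 8.24e-05), with the antiviral GTPase gene Mx2 at −2.15 ± 0.10. Erythroid markers fell, 4 of 11 (median −0.76, adjusted p = 0.000701), with Eraf at −1.71 ± 0.19 and Hba-a1 at −1.18 ± 0.074. Glutathione S-transferases had a median of −0.47 with 1 of 21 called, Gsta4 at −1.50 ± 0.069 (list adjusted p = 0.00142), and male-biased genes rose, 4 of 15 (median 0.37, adjusted p = 0.0126), with Elovl3 at 3.50 ± 0.058. These calls held with an estimated correlation.

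Mt1 rose by 1.84 ± 0.12, Mt2 by 1.25 ± 0.14 and Hamp1 by 1.73 ± 0.15 at DR6, and Tfrc fell by 1.37 ± 0.051, while Slc39a5 stood at 0.28. The metal list had 4 of 22 members higher and 3 lower, a median of −0.07 with a mean of 0.09 and a downward test, and no call (adjusted p = 0.818). Cyp1a1 rose by 2.05 ± 0.19 and Tiparp by 2.61 ± 0.11, with Cyp1a2 at −0.09 ± 0.071 and the AHR list at a median of 0.55 without a call (adjusted p = 0.0823). Cyp2b10 fell by 1.15 ± 0.087, the opposite direction to DR4, but the mean of its probes gave −0.87. Hmox1 (0.35 ± 0.096) and Nqo1 (−0.41 ± 0.10) were under the limit. Scd1, the desaturase that makes monounsaturated fatty acids, rose by 3.68 ± 0.070 in a fatty acid synthesis list with a median of −0.25 and no call (adjusted p = 0.165).

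The DR6 calls that did not hold were macrophage markers (median −0.39, adjusted p = 0.000698; adjusted p = 0.125 with an estimated correlation), with Marco at −2.22 ± 0.085, CAR and PXR targets (median −0.18, adjusted p = 0.00479; adjusted p = 0.113 with an estimated correlation), with Cyp2c37 at −1.69 ± 0.067, urea cycle and amino acid breakdown (median 0.55, adjusted p = 0.00479; adjusted p = 0.0507 with an estimated correlation), with Got1 at 1.81 ± 0.068, T and NK cell markers (median 0.40, adjusted p = 0.0171; adjusted p = 0.186 with an estimated correlation), clock genes (median 0.36, adjusted p = 0.0257; adjusted p = 0.0713 with an estimated correlation), with the clock repressor Gm129 at 2.30 ± 0.091, complement (median −0.14, adjusted p = 0.0422; adjusted p = 0.275 with an estimated correlation) and exocrine pancreas (median 0.26, none of 14 past 2-fold, adjusted p = 0.0179; adjusted p = 0.0507 with an estimated correlation). Female-biased genes (median −0.18, adjusted p = 0.16) and PPARα targets (median −0.16, adjusted p = 0.086) were not called. Cholesterol synthesis had a median of −0.04 with a mean of 0.06 and an upward test (adjusted p = 0.389), and cell cycle genes a median of 0.05, which changed sign under median scaling and normexp, with a mean of 0.07 and a downward test (adjusted p = 0.511). Heat shock genes (median −0.08, mean 0.08, adjusted p = 0.908) and ER stress genes (median −0.05, mean 0.15, adjusted p = 0.60) had upward tests without a call.

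The largest fitted rises at DR6, beside Atf3 and Scd1, were in Btc (4.71 ± 0.11), Rnf183 (at least 10.3-fold, a call lost without DR6 replicate 2 at adjusted p = 0.0607), the adrenergic receptor Adra2a (4.54 ± 0.062), Cacnb4 (at least 7.72-fold), the intestinal transcription factor Cdx2 (at least 3.87-fold), Reg3a (3.98 ± 0.089), the leptin receptor Lepr (3.69 ± 0.047) and Npy (3.66 ± 0.13). The largest fitted falls were in genes of squamous epithelium, Krt15 (at least 2.27-fold), Crct1 (at least 2.45-fold), Serpinb12 (at least 1.73-fold by its bound) and Asprv1 (at least 3.73-fold), and in Gluld1 (at least 6.92-fold), Cdh11 (−2.61 ± 0.36), Ostb (−2.57 ± 0.13), Fanca (at least 2.35-fold), the manganese transporter Slc30a10 (−2.23 ± 0.090) and Marco. Of 1136 genes called 763 were higher and 373 lower, 765 had a symbol, 242 rested on a bound, 38 had no signal above background at either site, and 7180 passed the adjusted p alone. The share of calls that were higher was 67.2%, 55.8% under median scaling, 60.1% under quantile scaling and 75.5% under normexp. With normexp and quantile scaling 47 of 95 named genes that were called lost their call, among them Cyp1a1 (0.96), Tfrc (−0.92), Fos (0.83), Mx2 (−0.96) and Eraf (−0.43).

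**Figure D2:**
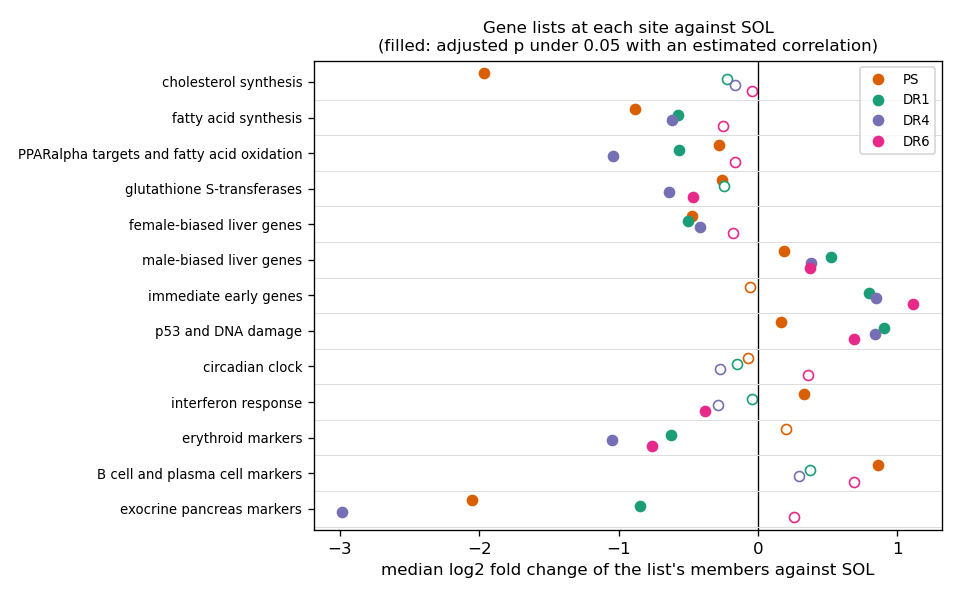
Median log2 fold change against SOL (horizontal axis) of 13 of the 36 gene lists, 1 point per polluted site, filled where the adjusted p with an estimated correlation was under 0.05. Exocrine pancreas markers lie lowest at DR4 (−2.98) and PS (−2.05), cholesterol synthesis is low at PS (−1.97), and immediate early genes are above 0.7 in the 3 stream pools and near 0 at PS (−0.06).

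The next question was what the 4 polluted pools shared. In all 4 site comparisons 116 genes were called in the same direction, 87 higher and 29 lower. Among them were Cyp26a1, which breaks down retinoic acid (at least 4.73-fold at DR6, where its change was smallest), and the pheromone carriers Mup5 (smallest change 2.03) and Mup4 (saturated at PS, DR1 and DR4, at least 2.82-fold at DR1). Higher at every site were also the muscle ubiquitin ligase Trim63 (1.95), Kcnab1 (1.82), Resp18 (1.80), the surfactant protein gene Sftpd (a bound at each site, at least 1.81-fold at DR1), Tspan1 (1.71), the melanocortin receptor Mc1r (1.62), Fmn2 (1.58), Serpina4-ps1 (1.57) and Abra (1.52). Lower at every site were Cdh11 (−2.19), Fanca (a bound at each site, at least 2.35-fold at DR6), Chrna2 (at least 2.74-fold at DR6), the steroid dehydrogenase Akr1c18 (−1.38), Hao3 (−1.36), Atp2b2 (−1.29), alkaline phosphatase Akp2 (−1.29), Itgb1bp3 (−1.26), Casc4 (−1.25), Mfsd7 (−1.24), glycerol phosphate dehydrogenase Gpd1 (−1.17) and the dopamine receptor Drd2 (at least 1.65-fold by its bound at DR6). The Drd2 call at DR6 was lost without SOL replicate 1 (adjusted p = 0.0913), SOL replicate 2 (adjusted p = 0.058), DR6 replicate 2 (adjusted p = 0.133) or DR6 replicate 3 (adjusted p = 0.104). Under normexp and quantile scaling 18 of these 24 genes lost their call at 1 or more sites, and 12 at all 4: Resp18, Sftpd, Tspan1, Abra, Cdh11, Fanca, Chrna2, Akr1c18, Itgb1bp3, Casc4, Mfsd7 and Drd2. Mup5, Mup4, Trim63, Serpina4-ps1, Hao3 and Gpd1 kept their call at every site. Mt1, Hamp1 and Gpx3 were also higher at each of the 4 sites, Gpx3 by 1.10 ± 0.13 at DR1, where its value was 0.93 without DR1 replicate 2, and by 1.80 ± 0.14 at DR6, but both calls were lost under normexp, at 0.35 and 0.72. The mean of all probes of Fmn2 ended its call at PS (0.38), DR1 (0.56) and DR6 (0.87), and that of Gpd1 at PS (−0.96) and at DR1 (adjusted p = 0.0546).

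**Figure D3:**
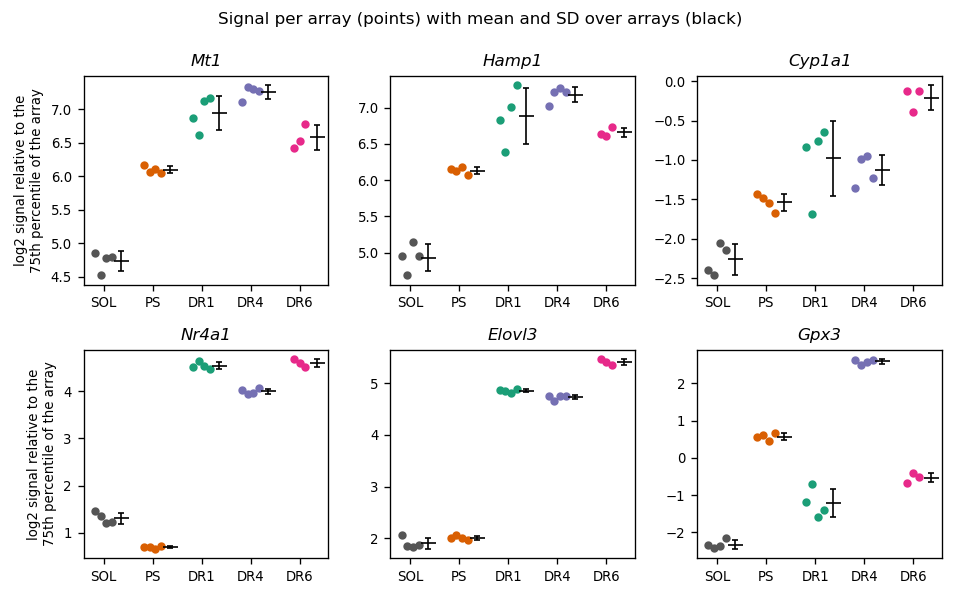
Signal of Mt1, Hamp1, Cyp1a1, Nr4a1, Elovl3 and Gpx3 on each array (points) by site, as log2 signal minus the array's 75th percentile, with the mean and SD over the arrays of a site (black). Mt1 lies between 4.52 and 4.85 on the 4 SOL arrays and at 6.04 or above on every array of the polluted sites; Nr4a1 lies at 0.73 or below at PS and at 3.93 or above in the 3 stream pools.

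Because the 4 comparisons share the SOL arrays, their overlap was set against simulations. With pools that differed from each other as the polluted pools do and no shared response, 20 simulations gave 133 to 179 shared genes, with a mean of 156.2. The 116 found lay below that range. These simulations added array noise to a spread that already held some, so they can overstate the overlap and cannot decide whether the pools share a response. With array spread alone they gave 0, and 4 independent lists would share 0.0327 genes higher and 0.0106 lower. Fold changes of pairs of sites correlated at r = 0.364 to 0.660 across genes, at 0.218 to 0.551 when each site was set against different SOL arrays, and at a mean of 0.497 in the simulated pools. All SOL arrays repeat 1 pool, so dividing them takes out shared array noise but not the shared SOL pool. With the 5 pools as the units, limma called 0 genes between the 4 polluted pools and SOL, with 665 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. With the pools as units and the preset correlation, 15 lists were called, but none with an estimated correlation, where the smallest adjusted p was 0.542. Medians in that fit were −0.61 for fatty acid synthesis (adjusted p = 1.13e-05; adjusted p = 0.542 with an estimated correlation), 0.69 for p53 targets (adjusted p = 1.13e-05; adjusted p = 0.542 with an estimated correlation), −0.51 for PPARα targets (adjusted p = 1.13e-05; adjusted p = 0.748 with an estimated correlation) and −1.45 for exocrine pancreas (adjusted p = 0.000452; adjusted p = 0.748 with an estimated correlation).

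Within the stream, the lower course was compared with the upper course. Clock genes were lower at DR1 than at DR6, 5 of 18 down and 1 up (median −0.82, adjusted p = 0.000593), with Gm129 at −1.28 ± 0.091 and Arntl at 1.65 ± 0.42. PPARα targets fell, 6 of 35 (median −0.50, adjusted p = 6.02e-05), with Acot2 at −1.93 ± 0.067 and Cyp8b1 at −1.64 ± 0.12. Interferon genes rose, 4 of 33 (median 0.57, adjusted p = 0.000408), with Mx2 at 1.35 ± 0.10, and cell cycle genes rose, 5 of 26 (median 0.63, adjusted p = 0.000611). Immediate early genes fell, 6 of 22 down and 1 up (median −0.24, adjusted p = 0.0106), with Atf3 at −2.81 ± 0.087 and Btg2 at −2.25 ± 0.073. Fatty acid synthesis fell, 3 of 21 (median −0.27, adjusted p = 0.00501), with Scd1 at −2.78 ± 0.070. Exocrine pancreas markers fell, 8 of 14 (median −1.10, adjusted p = 1.19e-09). Heat shock genes (median −0.23, adjusted p = 0.0183; adjusted p = 0.0502 with an estimated correlation), cholesterol synthesis (median −0.37, adjusted p = 0.00589; adjusted p = 0.0557 with an estimated correlation) and macrophage markers (median 0.31, adjusted p = 0.00298; adjusted p = 0.211 with an estimated correlation) were called with the preset correlation alone.

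The largest fitted rises from DR6 to DR1 were in Serpinb12 (at least 5.32-fold), Mlf1ip (at least 3.64-fold), Chi3l4 (at least 7.22-fold), Adh6-ps1 (at least 7.83-fold) and Asprv1 (at least 4.73-fold). The bound of Serpinb12 leans on 1 array: its fitted change fell from 4.39 to 3.13 without DR1 replicate 1. Among the largest fitted falls were Adra2a (−4.14 ± 0.062), Cdx2 (at least 4.38-fold), the cardiac calcium pump regulator Pln (at least 5.49-fold) and Csad (−3.94 ± 0.085), an enzyme of taurine synthesis. In all 1226 genes were called, 533 higher and 693 lower at DR1, 806 with a symbol, 253 on a bound and 21 without signal above background at either site, and 8308 passed the adjusted p alone. Calls that were higher made up 43.5%, 55.4% under median scaling, 50.1% under quantile scaling and 35% under normexp. With normexp and quantile scaling 5 of the 10 named genes were no longer called.

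The medium course was then compared with the upper course. PPARα targets fell at DR4, 13 of 35 and none rose (median −0.71, adjusted p = 2.90e-15), with Acot3 at −2.85 ± 0.079, Acot2 at −2.23 ± 0.067 and Fgf21 at −1.92 ± 0.44. Clock genes fell, 10 of 18 down and 1 up (median −1.13, adjusted p = 1.17e-05), with Gm129 at −2.40 ± 0.091, Per2 at −2.25 ± 0.16 and Arntl at 2.56 ± 0.42. Fatty acid synthesis fell, 4 of 21 (median −0.55, adjusted p = 0.00123), led by Scd1 at −4.27 ± 0.070. Interferon genes rose, 5 of 33 (median 0.29, adjusted p = 1.24e-05), with Rsad2 at 1.86 ± 0.14 and Ifit1 at 1.33 ± 0.21, and heat shock genes had 2 of 21 lower and 1 higher (median −0.35, adjusted p = 0.00123), with Hspa1b at −1.64 ± 0.098. All 14 exocrine pancreas markers fell (median −3.23, adjusted p = 1.04e-20). Each of these calls held with an estimated correlation.

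The largest fitted rises from DR6 to DR4 were in Chi3l4 (at least 20.7-fold), Chi3l3 (4.62 ± 0.14), Mlf1ip (at least 4.04-fold), Serpinb12 (at least 2.85-fold) and Calml3 (at least 3.26-fold). The largest fitted falls were in Defa1 (at least 15.4-fold), Defcr6 (at least 11.4-fold), Trim12 (at least 11.9-fold), the elastase Ela1 (−4.72 ± 0.063) and Pln (at least 6.26-fold). The comparison called 1007 genes, 390 higher and 617 lower at DR4, 685 with a symbol, 214 on a bound and 20 without signal above background at either site, and 7259 passed the adjusted p alone. Calls that were higher made up 38.7%, 49.2% under median scaling, 46.1% under quantile scaling and 35.7% under normexp. With normexp and quantile scaling 5 of the 10 named genes were no longer called.

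Between the lower and the medium course, cell cycle genes were higher at DR1, 14 of 26 and none lower (median 1.05, adjusted p = 4.22e-05), with the mitotic checkpoint kinase Bub1 at 1.43 ± 0.54 and Ccnd1 at 1.03 ± 0.056. PPARα targets were higher at DR1, 5 of 35 (median 0.38, adjusted p = 1.31e-06), with Fgf21 at 2.15 ± 0.41 and Acot3 at 1.34 ± 0.073, and so were glutathione S-transferases, 3 of 21 (median 0.38, adjusted p = 0.000145), with Gstt2 at 1.07 ± 0.088 and Mgst3 at 1.06 ± 0.057. All 14 exocrine pancreas markers were higher at DR1 (median 2.20, adjusted p = 5.59e-17). These 4 calls held with an estimated correlation. Macrophage markers (median 0.33, adjusted p = 0.00152; adjusted p = 0.193 with an estimated correlation), complement (median 0.32, adjusted p = 0.00152; adjusted p = 0.145 with an estimated correlation), oxidative phosphorylation (median 0.20, adjusted p = 0.00152; adjusted p = 0.0974 with an estimated correlation), erythroid markers (median 0.42, adjusted p = 0.0148; adjusted p = 0.0709 with an estimated correlation), antioxidant enzymes (median 0.32, adjusted p = 0.0427; adjusted p = 0.258 with an estimated correlation), clock genes (median 0.59, adjusted p = 0.0427; adjusted p = 0.0974 with an estimated correlation) and immediate early genes (median −0.28, adjusted p = 0.0438; adjusted p = 0.0974 with an estimated correlation) did not.

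The largest fitted rises from DR4 to DR1 were in Trim12 (at least 18.2-fold), Reg3a (5.02 ± 0.083), Pap (4.45 ± 0.090), Reg3g (at least 4.97-fold) and Chgb (4.03 ± 0.098). The largest fitted falls were in Npy (−5.07 ± 0.12), Cacnb4 (−4.07 ± 0.31), Gpx3 (−3.81 ± 0.13), Ddx25 (−3.53 ± 0.23) and Usp26 (at least 3.76-fold). Of 841 genes called 498 were higher and 343 lower at DR1, 562 had a symbol, 182 rested on a bound, 6 had no signal above background at either site, and 7312 passed the adjusted p alone. Of the 10 named genes 2 were no longer called with normexp and quantile scaling.

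**Figure D4:**
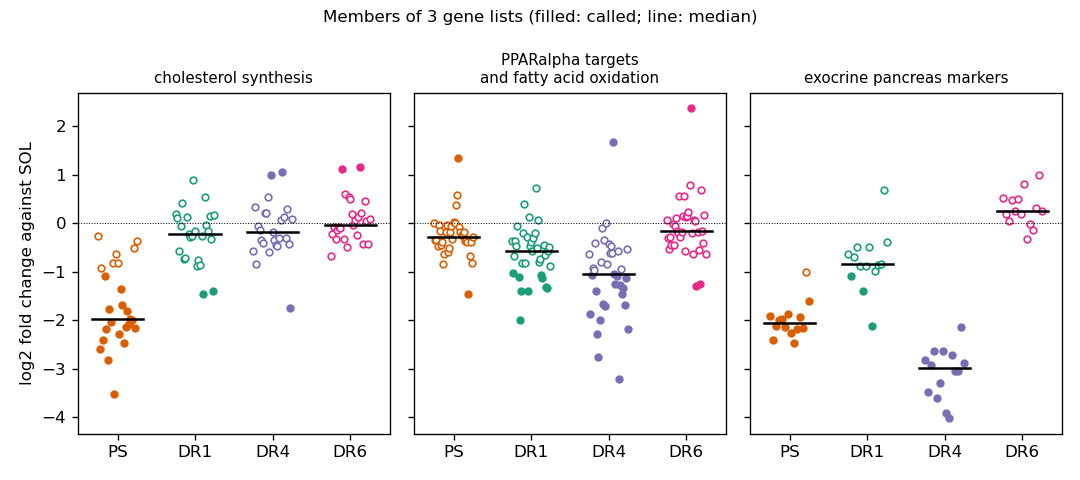
Log2 fold change against SOL of each measured member of the cholesterol synthesis, PPARα and exocrine pancreas lists (points, filled where called), by polluted site, with the list median (line). At PS 18 of 25 cholesterol genes are called lower, and at DR4 18 of 35 PPARα targets and all 14 pancreas markers are.

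Each site was also set against the other 4. With the pools as units, limma called 1 gene that set PS apart, Kap (adjusted p = 0.00391), 1 that set DR4 apart, A130022J15Rik (adjusted p = 0.00199), and 1 that set DR6 apart, Cdx2 (adjusted p = 0.0385); 546, 1072 and 853 genes had an unadjusted p under 0.05. These 3 genes lay at background in the other 4 pools: of the arrays there 1 of 15 was well above background for Kap, 0 of 15 for A130022J15Rik and 0 of 16 for Cdx2. The spread behind these p-values is thus that of signals at background, not of differences between pools, and the same kind of fit gave 7 false calls in a test on simulated pools. A130022J15Rik was named after its value was seen. For DR1 limma called 0 genes, with 665 at an unadjusted p under 0.05 and a smallest adjusted p of 0.156. On the arrays, 169 genes at DR4 were called against each of the 4 other sites in the same direction, 68 higher and 101 lower, 116 at SOL (29 higher and 87 lower), 106 at PS (51 and 55), 101 at DR6 (69 and 32) and 73 at DR1 (39 and 34). The Kap call was lost without DR1 or without DR6, with 0 genes each, and the Cdx2 call without any 1 of the other pools.

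Counts of called list members were the same when the p-values were adjusted over the list alone as over all genes, except for ER stress genes. At DR4 against SOL these had 5 higher and 3 lower of 27 when adjusted over the list alone, and 4 higher and 3 lower over all genes. For DR4 against DR6 they had 2 higher and 4 lower over the list alone, and 1 higher and 4 lower over all genes.

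List medians use fitted values, which are no bounds for members at background. They were therefore computed again with each such member at its bound and without members at background in both sites. Of the medians given above, these moved by 0.05 or more. At PS the median of B cell markers became 0.60, of T and NK cell markers 0.47, of neutrophil markers 0.13 and of cell cycle genes −0.17. At DR1 the median of cell cycle genes became 0.53 and of B cell markers 0.44. At DR6 the median of cell cycle genes changed sign, to −0.20. T and NK cell markers at DR6 became 0.23, erythroid markers −0.87 and female-biased genes −0.13. Cell cycle genes became 0.55 for DR1 against DR6 and 0.98 for DR1 against DR4, where clock genes became 0.48.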

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

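Tests of pancreatic islet genes, of the PS median of immediate early genes, of clock genes between DR4 and DR6 and of Y-linked genes were chosen only after the results were seen.

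Exocrine pancreas genes fell at PS and DR4 and had the widest range of medians among the 36 lists. Their members are bright: Amy2-2 lay 8.27 above the 75th percentile at SOL and 5.45 at DR4 on the log2 scale. Against a slide or scan effect on probes of that signal, the list lay at percentile 0 of random lists of the same signal at both sites. A candidate explanation is unequal amounts of pancreas in the pooled tissue. The islet list, which shares no gene with the exocrine list, had a median of −2.43 at PS and −2.0 at DR4. With members at background placed at their bound these were −1.11 and −1.18. With an estimated correlation its adjusted p was 0.00265 at PS and 0.0614 at DR4. At both sites 5 of 8 members were called lower. Not called were Iapp (−0.67 at PS and −0.39 at DR4), Pcsk2 (−0.67 and −0.46) and Nkx6-1 (−0.33 and −0.41). At DR1 the exocrine list had a median of −0.84, but the islet list had −0.33 and no call (adjusted p = 0.213 with an estimated correlation). A difference of pancreas RNA within livers, dissection, a slide effect that does not follow signal and the site itself stay open, since each pool is 1 sample on 1 slide.

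Immediate early genes rose in the 3 stream pools and not at PS. Against a low SOL pool as the whole cause, the PS median was −0.058, while the smallest stream median was 0.79. Against 1 time-of-day shift shared alike by the stream pools, clock genes differed between DR4 and DR6 (adjusted p = 0.00176 with an estimated correlation). That difference does not speak against sampling times that differed between the pools. Against a slide effect on probes of that signal, the list lay at percentile 100 of random lists in all 3 comparisons. These genes respond to handling within minutes, so differences in capture, time to dissection or exposure may account for the pattern, as may time of day. The design, with 1 slide and 1 pool per site, cannot separate these.

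Male-biased genes were higher and female-biased genes lower in polluted pools than at SOL, except that female-biased genes at DR6 were not called. A SOL pool that was mostly female liver is argued against by the Y-linked genes Ddx3y, Eif2s3y and Jarid1d, whose median difference between SOL and the polluted pools was −0.10, with an SD of 0.098 over the 3 genes. For a smaller female share the planned test on Xist could not decide. Its smallest difference, SOL minus a polluted pool, was −0.80, but 1 of 76 probe and array pairs was well above background. The rule that voids the test at background was added after that was seen. At SOL 0 arrays were well above background for any of the 4 Xist probes. An absence of Xist there would go against female liver, but every pool is described as male. No array here shows whether these probes detect Xist. Against a slide effect on probes of that signal, the called lists lay within 1.64 percentiles of the end of the random lists. Hormone status, age, exposure, a small share of female liver and a slide effect that does not follow signal stay open.

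The count of called genes in each comparison was set against other splits of the arrays of its 2 sites: among the 35 splits, 1, the sites themselves, gave a count as high. The counts of the sites and the highest of the other splits were 698 and 1 for PS against SOL, 927 and 0 for DR1 against SOL, 1672 and 1 for DR4 against SOL, 1069 and 62 for DR6 against SOL, 1172 and 14 for DR1 against DR6, 1010 and 4 for DR4 against DR6 and 818 and 1 for DR1 against DR4. The arrays of a site repeat 1 pool on 1 slide, so these splits set single samples against array noise. They exclude neither chance between mice nor a slide effect.

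Some arrays lay far from the others of their site by Dixon's test, which picks out about 1 in 20 groups by chance, and 40 array measures were tested. DR4 replicate 2 had 61.5% of spots well above background, against 55.9% to 56.5% on the others. Median background was 37 on SOL replicate 4 against 38, and 45 on DR1 replicate 4 against 46. The detection limit of the spiked controls was 1.26 (log10) on SOL replicate 4, against 0.595 to 0.70. SOL replicate 1 had a mean correlation of 0.981 with its site, against 0.989 to 0.990. Among named genes, 21 of 209 at SOL had 1 array far from the others (14 times replicate 1), 17 of 215 at PS (9 times replicate 4), 18 of 214 at DR1 (7 times replicate 2) and 12 of 212 at DR4 (7 times replicate 2); among all genes the shares were 8.49%, 6.76%, 6.51% and 6.14%.

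Changes against SOL in opposite directions at 2 sites were set against each other directly, with camera and an estimated correlation. Lists were taken if called at both sites with the preset correlation, and kept if the difference had an adjusted p under 0.05. The p-values here are thus part of the selection and no separate support. Interferon response genes were higher at PS than at DR6 by a median of 0.82 (adjusted p = 2.91e-06). Exocrine pancreas markers differed from DR6 by −2.20 at PS (adjusted p = 2.91e-06), by −1.10 at DR1 (adjusted p = 0.000236) and by −3.23 at DR4 (adjusted p = 2.61e-06). Clock genes differed between DR4 and DR6 by −1.13 (adjusted p = 0.00176). The differences of DR1 and DR4 from DR6 repeat the stream comparisons above. Against SOL, the clock calls at DR4 and DR6 and the exocrine pancreas call at DR6 did not hold with an estimated correlation.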

How the results depend on the processing

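Leaving out both arrays that correlated least with their site, leaving out other-organ genes, and leaving SOL out of the fit of pools, were tests chosen only after the results were seen. Where they were computed under another setting, no gene list (4428 values) and no named gene (14326 values) reversed a called direction. Quantile scaling, median scaling, the series value table, the fit on the arrays of the 2 sites and the 1.5-fold test left each count of called genes within 1.5 times the reported one.

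Normexp with quantile scaling lowered every count of genes called between sites: 196 for PS, 245 for DR1, 596 for DR4 and 277 for DR6 against SOL, 300 for DR1 against DR6, 241 for DR4 against DR6 and 193 for DR1 against DR4. It gave 21 genes shared by the 4 polluted sites, 21, 27, 5, 36 and 18 genes that differ from all 4 other sites for SOL, PS, DR1, DR4 and DR6, and 0 genes in the fit of pools for PS and for DR6. Its offset of 50 pulls dim signals together by construction, and 191 of the 423 calls of named genes were lost with it. With only probes well above background on all arrays, which tests fewer genes, the counts were 390 for PS, 551 for DR1 and 661 for DR6 against SOL, 693 for DR1 against DR6, 603 for DR4 against DR6 and 446 for DR1 against DR4. It gave 61 genes shared by the 4 sites, 61, 54, 26, 92 and 51 genes apart at SOL, PS, DR1, DR4 and DR6, and 0 in the fit of pools for PS, DR4 and DR6. Without the filter 153 genes set DR6 apart, and with the mean of all probes the fit of pools called 2 genes for DR4. For these the cause was not tested.

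With the adjusted p alone, which drops the 2-fold limit, the counts were 5364 for PS, 7796 for DR1, 8982 for DR4 and 7180 for DR6 against SOL, 8308 for DR1 against DR6, 7259 for DR4 against DR6 and 7312 for DR1 against DR4. It gave 1453 shared by the 4 sites and 1453, 1147, 1551, 2323 and 1485 apart at SOL, PS, DR1, DR4 and DR6. With arrays in place of pools as replicates, which tests against array spread, the polluted sites against SOL gave 686 genes (434 higher, 252 lower), and SOL, PS, DR1, DR4 and DR6 against the others gave 686, 638, 459, 872 and 687. Without other-organ genes the fit of pools called 0 genes for PS and 0 for DR6, since Kap and Cdx2 are on those lists.

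Leaving out 1 array gave 701 to 759 genes for PS, 964 to 1082 for DR1, 1671 to 1789 for DR4 and 1041 to 1183 for DR6 against SOL, 1160 to 1281 for DR1 against DR6, 977 to 1030 for DR4 against DR6 and 814 to 912 for DR1 against DR4. It gave 109 to 126 genes shared by the 4 sites, 80 to 89 list calls (86 reported), and 109 to 126, 99 to 115, 66 to 84, 163 to 179 and 98 to 121 genes apart at SOL, PS, DR1, DR4 and DR6. Leaving out 1 pool gave 0 to 1 genes for PS (0 without DR1 or DR6), 0 to 0 for DR1, 1 to 4 for DR4 (4 without DR6), 0 to 0 for DR6 against 1 with all pools, and 0 to 0 for SOL, which is also the polluted sites against SOL. Without SOL the counts were 1 for PS, 0 for DR1, 1 for DR4 and 0 for DR6. Without both low-correlation arrays 6 list calls were lost and 1 gained, and 13 calls of named genes were lost and 5 gained.

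Of the 86 list calls, 17 ended under 1 or more settings, and 1 of these, heat shock at DR4, had held with an estimated correlation. Against SOL the others were ER stress at PS, CAR and PXR targets at DR1, antioxidant enzymes, complement, oxidative phosphorylation, clock genes and endothelial markers at DR4, and complement, clock genes and T and NK cell markers at DR6. For DR1 against DR4 they were antioxidant enzymes, oxidative phosphorylation, clock genes, immediate early genes and erythroid markers, and for DR1 against DR6 cholesterol synthesis. By setting, 10 ended under normexp, 7 with only probes well above background, 6 under quantile scaling, 6 in the fit on the arrays of the 2 sites, 4 with a block for replicate number, 3 under median scaling, 3 with the mean of probes and 1 without the filter. Leaving out 1 array ended a list call 12 times.

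The replicate number is also the position on the slide. Deviations from the site means correlated at −0.162 to 0.483 between same-numbered arrays (36 pairs, mean 0.0923) and at −0.411 to 0.462 between the others (108 pairs, mean −0.0299). Not every array lay closest to its own number, but 11 of 19 did, a hint from the data that position has some effect. The numbers were not used as pairs. A block for replicate number gave 725, 997, 1730 and 1168 genes for PS, DR1, DR4 and DR6 against SOL and 1260, 1027 and 845 for DR1 against DR6, DR4 against DR6 and DR1 against DR4, 117 shared genes and 83 list calls. Signal over background limits which genes have more than a bound: from 182 (DR1 against DR4) to 295 (DR4 against SOL) calls per comparison rest on one.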

Other observations

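All lists in this part, and their tests, were chosen only after the results for single genes were seen. Adjusted p-values are from camera with an estimated correlation. A second median, where given, has members at background placed at their bound. At DR6 genes of stomach and intestine rose against SOL, 9 of 14 (median 2.04, or 1.66 with bounds, adjusted p = 0.0214). Among them were the intestinal transcription factor Cdx2 (at least 3.87-fold), the Paneth cell defensins Defa1 (2.13) and Defcr6 (2.26) and Clca3 (2.49). The brightest gene of the list, Fabp2, went the other way: its log2 level above the 75th percentile was 5.91 at SOL and 4.98 at DR6. At PS 7 of 14 were lower and 2 higher (median −0.91, or −1.06 with bounds, adjusted p = 0.0698). From DR6 to DR4 11 of 14 fell (median −3.59, or −2.34 with bounds, adjusted p = 0.00268). Genes of squamous epithelium fell at DR6, 7 of 14 (median −1.16, adjusted p = 0.0214), but 6 members had only a bound there and the median with bounds was −0.43. They fell at PS too, 6 of 14 (median −0.64, or −0.52 with bounds, adjusted p = 0.0174). The brightest, Lor, had a level of 1.30 at SOL and −0.26 at DR6.

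Islet genes fell at PS, 5 of 8 (median −2.43, or −1.11 with bounds, adjusted p = 0.00265), among them glucagon, Gcg (at least 6.06-fold), insulin, Ins1 (−2.59), and somatostatin, Sst (at least 2.91-fold). The brightest, Ins2, had a level of −0.02 at SOL and −3.17 at PS. Iapp (−0.67), Pcsk2 (−0.67) and Nkx6-1 (−0.33) were not called at PS. At DR4 5 of 8 were lower (median −2.0, or −1.18 with bounds, adjusted p = 0.0614), and at DR6 3 of 8 were higher (median 0.63, adjusted p = 0.0909). Genes of the adrenal gland had 3 of 8 higher at PS (median 0.33, adjusted p = 0.0207), the steroid synthesis genes Star (2.20) and Cyp11a1 (at least 2.16-fold) and Chgb (at least 46.6-fold). The brightest at SOL, Hsd3b1, had a level of −0.00 at SOL and −0.10 at PS, and Mc2r (−0.18), Nr5a1 (−0.22) and Pnmt (−0.02) did not rise. At DR1 4 of 8 were higher, without a call of the list (median 0.59, or 0.43 with bounds, adjusted p = 0.0836). Skeletal muscle genes rose at DR1, 5 of 11 (median 0.85, adjusted p = 0.00434), with the fast myosin Myh4 at 2.85. They rose at DR6, 2 of 11 (median 0.69, adjusted p = 0.00247), and at PS, 1 of 11 (median 0.26, adjusted p = 0.0142). The brightest, Tnnc2, had a level of 4.12 at SOL and 5.17 at DR1, while Ckm (−0.47) and Acta1 (−0.18) did not rise at DR1. Kidney genes at PS had 4 of 10 higher and 1 lower (median 0.18, or 0.10 with bounds, adjusted p = 0.522), with Kap (at least 10.5-fold), Umod (2.24) and Slc34a1 (at least 1.39-fold), while the brightest, Ren1, had levels of 2.42 at SOL and 2.06 at PS. Lung genes were not called at PS (median −0.29, adjusted p = 0.989), DR1 (median 0.19, adjusted p = 0.480), DR4 (median 0.08, adjusted p = 0.236) or DR6 (median 0.63, adjusted p = 0.0909).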
